A study of Mus musculus with 24 samples.

How the data were processed

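Epididymal white adipose tissue RNA of 24 male mice, 12 per diet, was analysed from 24 Agilent 2-colour arrays of 62976 spots. Per the labels' protocols, the Cy5 channel held the cRNA of 1 mouse and the Cy3 channel a reference pool that also contained other diets and females. All arrays ran in the same dye orientation, so a probe-specific dye bias enters every ratio alike and cancels in the difference between diets. The animal number in the labels named each replicate. The 2 diets shared no animal, so nothing paired the mice. Slides were told apart by the slide code of each array and numbered 1 to 5. Per the file headers, the arrays of each slide share 1 scan time, all on 1 day, so slide and scan are the same batch here. No array pair had identical Cy5 signals.

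The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction 10.7.3.1 per the file headers and the submitters' processing notes. Flags for outliers, saturation and signal over background are given as yes or no per spot, per the file headers. The files hold median spot intensities, and the authors' deposited processed intensities, which were already background-subtracted and dye-normalized per the file headers. Mean spot signals had been intended as input; the median spot signals of the files were used in their place, also where no background was subtracted. The authors' value table holds log2 values for 26384 features. Its columns followed the log2 Cy5 median signal of their own array (r at least 0.99) and not the log ratio (r at most 0.278), and every column had a median of 8.04. Its scale is therefore that of log2 Cy5 intensity in which higher means brighter, while the method of its normalization and its filter are not given in the sources used here. It served as an alternative.

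Background was corrected with normexp and an offset of 50, and ratios were normalized within arrays by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and outlier-flagged spots were then left out, and spots of the same probe were averaged, which gave 55681 probes. A probe was kept when its Cy5 signal was well above background on at least 6 of the 12 arrays of either diet (24769 probes). The files name probes by accession. Without versions, 27235 of the 55681 probes matched 1 gene symbol in a RefSeq table (assembly GRCm38.p6, used for names and for the chromosomes of named genes) and 28446 matched none and kept their probe name. The file headers name the earlier build mm9, so no coordinates are given. A gene with several kept probes was represented by its brightest probe. Of the 3141 genes with more than 1 kept probe, 14 had probes that differed in sign, each at an unadjusted p under 0.05, and these were not named as leading genes. 6 features were well above background on no array of a diet, none of them named in the text.

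Diets were compared with limma (lmFit and eBayes, diet as the only term) on the log2 ratios, with Benjamini-Hochberg adjustment and a threshold of 0.05. 39 gene lists (pathways, cell types that fat or its surroundings could hold, tissue handling) were written down before the data were examined, as were the test, the naming rule and the first group of other settings given at the end. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Where slide was a random block, or variances followed intensity, the lists were tested on limma's statistics with cameraPR. Missing values (0.112%) were replaced by the mean of their diet for the list tests, list means, principal components and the set of features around the leading probe. Without this, the correlation of a list with the macrophage list changed by at most 0.00767. Single genes were fitted and related on their measured values. fry tests whether a list moves 1 way on balance and does not compare it with other genes. Per-mouse list means were compared by permutation tests with 100000 resamples, and related to each other across mice with permutation tests of r and rho; both were added after the data were seen. The genes named are, by the rule: up to 12 genes per direction with the largest change among those that passed, filled to 6 per direction with the lowest unadjusted p where fewer passed, leaving out clone and predicted names; the 2 members with the lowest p of each list that passed and of 8 lists on NAD, the clock, lipid synthesis, mitochondria, fat cells and macrophages; and a fixed set of NAD and adipocyte genes. A result that the rule would name but that is withheld is not reported here.

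The method was tested on simulated data built from the real residuals with shuffled arrays, in 20 runs with 200 of the 21051 features changed. Of features changed by 0.5 on the log2 scale 86.0% were called, of those changed by 1, 98.4%, and of those changed by 1.5, 99.7%, with a median of 4.5 false calls. The list of cytosolic ribosomal proteins, the only one shifted (by 0.3), was called in 20 of 20 runs. In 14 of the 20, 3 or more unshifted lists were called as well, with a median of 5. In the real data the means of the ribosomal list ran from -0.15 to 0.12 between mice, against -1.24 to 0.82 for macrophage markers. The calls of the shifted list therefore need not hold for lists that vary more. The shuffling keeps the genes of a list correlated. The changed features were drawn at random outside the lists, so the shares called need not hold for the features that vary most between mice. In the comparison of diets, 147 features had an absolute log2 fold change over 0.5, and 0 features were called.

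Other settings fixed at that time were the processed signals, no background subtraction, Aquantile normalization, median centring, the Cy5 channel alone, no filter and a stricter filter, slide as a fixed or random block, array weights, an intensity trend with robust variances, single probes, means of probes, the value table, leaving out each mouse in turn and, for lists, the estimated correlation and fry. Added after the data were seen were array weights by REML, leaving out the 3 arrays of weight under 0.6 and the mean of the macrophage list as a covariate. Probe sequences were not used here, so base composition was not examined.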

Results

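Transcript levels were measured in the epididymal white adipose tissue, the fat pad beside the testis, of 24 individually numbered adult male C57BL/6JRcc mice. For 18 weeks, 12 mice ate a semi-synthetic diet with 30 mg of nicotinamide riboside (NR, a form of vitamin B3 that cells turn into NAD) per kg as its vitamin B3 (Ctrl NR), and 12 ate the same diet with 0 mg (No NR). Tryptophan, from which NAD can also be made, was kept low but adequate in both diets, and the tissue was taken after a fast and a short refeeding. The Cy5-labelled RNA of each mouse was hybridised on its own array with a common Cy3-labelled pool of fat-pad RNA, which also held other diets and females. The arrays lay on 5 slides, each with mice of both diets. Slides 1 to 5 held 2, 2, 2, 4 and 2 Ctrl NR mice and 1, 3, 3, 2 and 3 No NR mice. Between 34.5% and 50.7% of the non-control spots of an array were well above background in Cy5, with a median of 44.7%. Values are log2 ratios of a mouse over the pool, given as mean ± SD with n = 12 mice per diet unless stated, and log2 fold changes are No NR minus Ctrl NR. The number of arrays limits the precision: the standard error of a log2 fold change had a median of 0.0811.

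The comparison of the diets asked how the transcripts of white fat respond when dietary vitamin B3 is withdrawn. As groups, macrophage markers (median log2 fold change 0.29) and cell cycle genes (0.23) were higher in No NR mice and endothelial markers lower (-0.16), by camera with a preset inter-gene correlation (adjusted p = 0.000426, 0.000426 and 0.0223). None of these calls held when the correlation was estimated from the mice (adjusted p = 0.926 with an estimated correlation for each). Among single genes, the lowest p-values were those of Anp32a, an acidic nuclear phosphoprotein, Mta1, a subunit of the NuRD chromatin remodelling complex, and Rtl8a, a retrotransposon-derived gene, all with lower values in No NR mice. None of these genes passed the threshold either, with a limma adjusted p of 0.0568 for all 3.

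Anp32a averaged 0.40 ± 0.30 in Ctrl NR and -0.55 ± 0.53 in No NR mice, a log2 fold change of -0.94 (SE 0.163, 0.521-fold). Mta1 was at -0.35 (SE 0.0621, 0.784-fold) and Rtl8a at -0.40 (SE 0.0733, 0.756-fold). Among 21051 features, 13014 named genes and 8037 unnamed probes, limma called 0 higher and 0 lower at an adjusted p under 0.05. At an adjusted p under 0.10 it listed 89 higher and 81 lower, and at an unadjusted p under 0.05 it listed 2968, of which 1446 were higher and 1522 lower, where 1053 would be expected on average with no effect. That count depended on the normalization: with median centring it was 264, of which 84 were higher and 180 lower. Other splits of the same mice gave a median of 796 and up to 5938. An absolute log2 fold change over 0.5 was seen in 147 features and one over 1 in 7.

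Among genes with established names, the next lowest p-values of genes lower in No NR mice were those of Ino80d, a subunit of the INO80 chromatin remodelling complex, at -0.59 (SE 0.119), Chtf8, a factor of sister chromatid cohesion, at -0.49 (SE 0.103), and Cpsf1, a subunit of the complex that cleaves and polyadenylates pre-mRNA, at -0.31 (SE 0.0647). The lowest p-values of genes higher in No NR mice were those of the U3 small nucleolar RNA Rnu3b1 at 0.67 (SE 0.140), the cation channel gene Trpm1 at 0.44 (SE 0.0920), Dpy19l4 at 0.23 (SE 0.0529), the kinase gene Map2k1 (MEK1) at 0.63 (SE 0.148), Tmem123 at 0.59 (SE 0.139) and the dynein light chain gene Dynlt3 at 0.47 (SE 0.112). The limma adjusted p of each of these further genes was 0.0764, so none passed. Dpy19l4 was well above background on 5 Ctrl NR and 9 No NR arrays, and the others on all 24. Of the 3 probes of Trpm1 on the array, 1 was kept by the filter, so its difference rests on that probe. All 12 genes named so far had the same sign within each of the 5 slides. They were picked for low p in these same arrays, so this agreement is in part built in. Some differences were near 0, as for Mta1 (-0.03) and Map2k1 (0.08) on slide 1. With slide as a block, limma gave -0.87 for Anp32a, -0.36 for Mta1, -0.40 for Rtl8a and 0.61 for Rnu3b1, and the smallest adjusted p of any feature was 0.139 (range over 41 alternative settings 0.00347 to 0.665).

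The other probe of Anp32a, the dimmer of 2, had a log2 fold change of 0.08 (unadjusted limma p = 0.439), so the difference rests on 1 probe, and the mean of both gave -0.43. The largest absolute change of any feature, singled out after its values were seen, was that of the unnamed probe A_55_P2138100, at -1.52 (SE 0.321, limma adjusted p = 0.0764). It averaged 0.22 ± 1.18 in Ctrl NR and -1.30 ± 0.33 in No NR mice. Its ratio lay above 0 in 7 of the 12 Ctrl NR mice and in 0 of the 12 No NR mice, and its within-slide differences ran from -0.49 on slide 1 to -2.71 on slide 5. Ino80d and Map2k1 belong to the 56 features that follow or oppose this probe from mouse to mouse within a diet. The other 10 genes followed the mean of these features to varying degrees within diets: r was 0.746 for Chtf8, -0.740 for Tmem123, -0.660 for Rnu3b1, -0.639 for Dynlt3, 0.562 for Rtl8a, 0.506 for Mta1, 0.502 for Cpsf1, 0.275 for Anp32a, -0.173 for Dpy19l4 and 0.0641 for Trpm1. With the mean of the macrophage markers, r within diets was -0.617 for Rtl8a, -0.498 for Anp32a and -0.436 for Mta1. The next in size among these genes was 0.376 for Dynlt3.

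**Figure D1:**
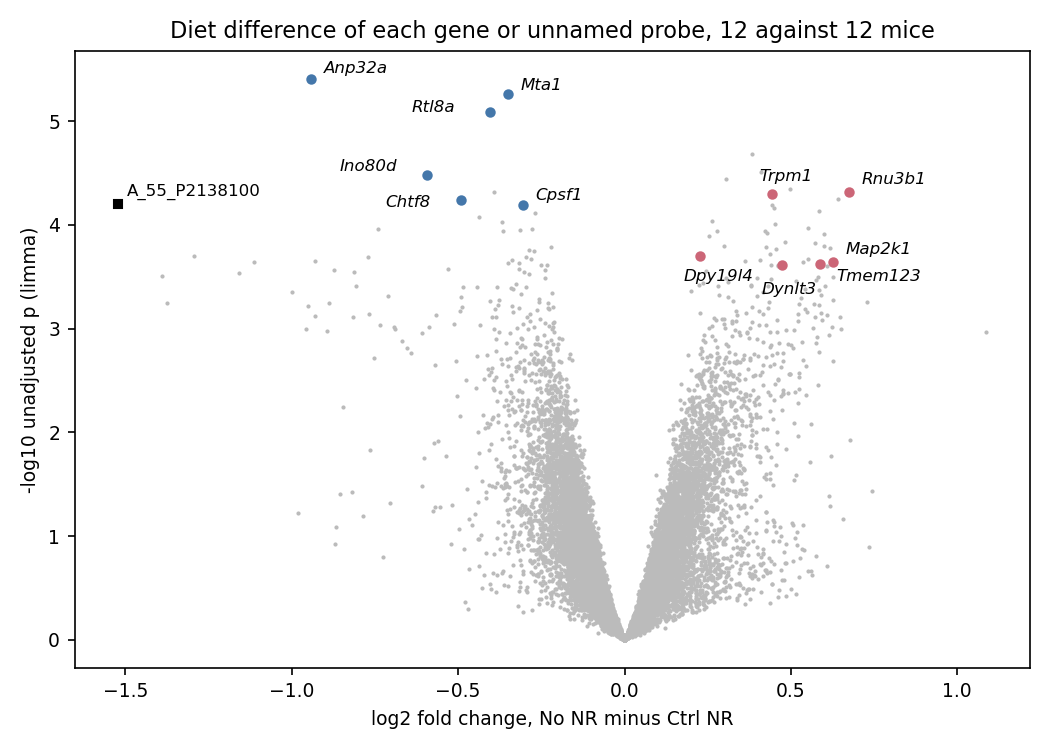
Each grey point is a gene or unnamed probe, with its log2 fold change (No NR minus Ctrl NR) on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis, from 12 mice per diet. The named blue (lower without NR) and red (higher) points are the 12 genes, 6 per direction, with the lowest p among established gene names, none of which passed an adjusted p of 0.05, and the black square is probe A_55_P2138100 at -1.52.

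**Figure D2:**
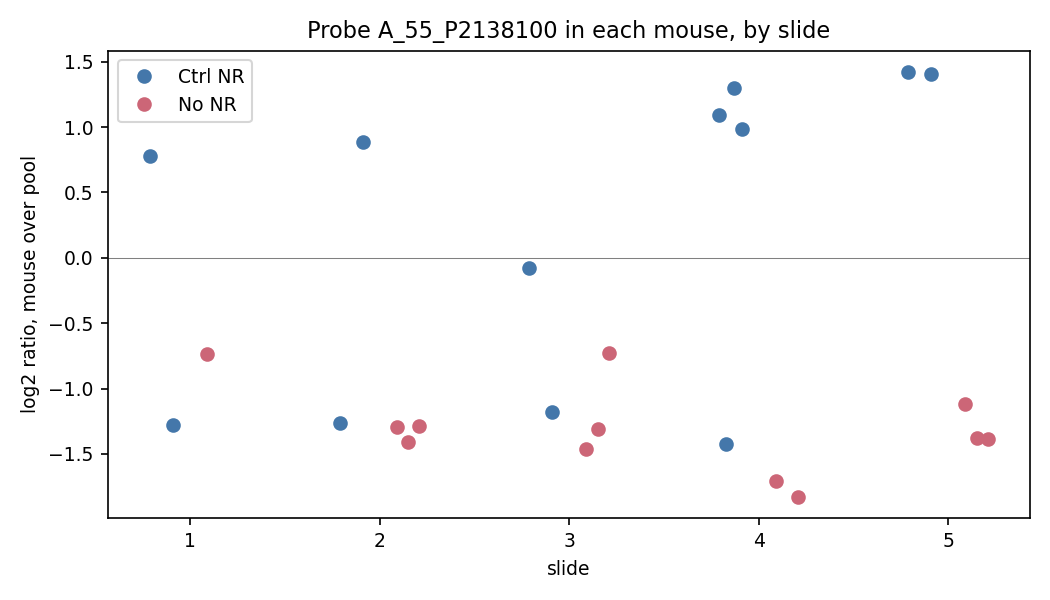
Log2 ratio of probe A_55_P2138100 (mouse over reference pool, vertical axis) in each of the 24 mice, by slide (horizontal axis) and diet (colour). All 12 No NR mice lie below 0, and 7 of the 12 Ctrl NR mice lie above it.

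Genes of NAD synthesis and salvage, a list not limited to the steps from vitamin B3 precursors, showed no difference between the diets that passed a test. Of the 12 measured members of the NAD synthesis and salvage list, 4 were higher and 8 lower in No NR mice, 0 had an unadjusted limma p under 0.05, and the median log2 fold change was -0.02 (camera adjusted p = 0.915). Nampt, the rate-limiting enzyme of NAD salvage from nicotinamide, was at 0.08 (95% interval -0.13 to 0.28), and Nmrk1, the kinase that phosphorylates NR, at -0.01 (-0.14 to 0.13). Naprt, which uses nicotinic acid, was at -0.08 (-0.24 to 0.08), Nmnat1 at -0.09 (-0.22 to 0.04) and Nmnat3 at 0.08 (-0.13 to 0.30). Pnp, which cleaves NR to nicotinamide, had the lowest p of the list at 0.17 (-0.05 to 0.39). Within diets, Pnp opposed the mean of the 56 features around probe A_55_P2138100 (r = -0.711). Nmnat2 was not well above background on any of the 24 arrays.

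Of the 18 measured genes that consume NAD or clear nicotinamide, 9 were higher and 9 lower, with a median of 0.01 (camera adjusted p = 0.946). Sirt3, the main mitochondrial deacetylase, had the lowest p, at -0.29 (-0.51 to -0.06, limma adjusted p = 0.236), from 0.32 ± 0.21 in Ctrl NR to 0.03 ± 0.33 in No NR mice. Aox1, an oxidase of nicotinamide metabolites, was at 0.20 (limma adjusted p = 0.351) and Parp1, a DNA-damage-responsive NAD consumer, at 0.20 (limma adjusted p = 0.354). Within diets, Parp1 opposed the mean of the 56 features around probe A_55_P2138100 (r = -0.675). Nnmt, which methylates nicotinamide, was at 0.02 (-0.22 to 0.25), Sirt1 at -0.08 (-0.32 to 0.16) and the NAD hydrolase gene Cd38 at -0.01 (-0.22 to 0.20). Of the 5 measured genes of the kynurenine pathway list, 1 was higher and 4 lower, with a median of -0.07 (camera adjusted p = 0.486). The list is not limited to the steps from tryptophan to NAD. It was led by Haao at -0.15 (limma adjusted p = 0.394) and Kyat3 at -0.25 (limma adjusted p = 0.439). Within diets, Kyat3 and Aox1 opposed the mean of the macrophage markers (r = -0.814 and -0.662), and Haao followed it (r = 0.565). Hcar2, the receptor for nicotinic acid, was at 0.08 (-0.06 to 0.21), and its other, dimmer probe at 0.15 (unadjusted limma p = 0.0385). In these 3 lists, 0 members passed adjusted over the list alone. The sign was not settled for Nmrk1 (the same in 26 of 40 alternative settings), Cd38 (28 of 41), Nnmt (33 of 41) and Nampt (40 of 41).

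Of the 30 measured macrophage markers, 29 were higher in No NR mice, 5 of them at an unadjusted limma p under 0.05. Of all 21051 features, 2968 were at that level in either direction. Itgam (CD11b) was at 0.21 and the Fc receptor gene Fcgr3 at 0.68 (limma adjusted p = 0.217 and 0.225). Itgam did not follow the list from mouse to mouse (r = -0.125 with the list mean within diets, against 0.902 for Fcgr3), and its other probe was at 0.12 (unadjusted limma p = 0.471). All 24 measured cell cycle genes were higher, led by the centromere gene Cenpa at 0.43 (limma adjusted p = 0.292) and the spindle gene Tpx2 at 0.31 (limma adjusted p = 0.391). Of the 21 measured endothelial markers, 18 were lower, 6 at an unadjusted p under 0.05, led by Cdh5 (VE-cadherin) at -0.33 (limma adjusted p = 0.254) and Eng (endoglin) at -0.21 (limma adjusted p = 0.295). No member of these lists passed over all genes or adjusted over the list alone.

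These were 3 of 39 lists tested, and fry gave an adjusted p of 0.667 for each. On average, the genes of each list moved together from mouse to mouse, with estimated inter-gene correlations of 0.597 for macrophage markers, 0.822 for the cell cycle and 0.410 for endothelial markers. Averaged per mouse, the macrophage list was at -0.15 ± 0.71 in Ctrl NR and 0.15 ± 0.59 in No NR mice, a difference within the spread between mice (2-sided permutation test, p = 0.263). The cell cycle list was at -0.12 ± 0.48 and 0.12 ± 0.44 (permutation p = 0.208), and the endothelial list at 0.06 ± 0.22 and -0.06 ± 0.19 (permutation p = 0.137). In that test 0 of the 39 lists had an adjusted p under 0.05, the lowest being 0.299.

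With slide as a block, camera with the preset correlation gave an adjusted p of 0.00931 for macrophage markers (range over all alternatives 5.72e-06 to 0.926), 0.00931 for the cell cycle (1.44e-07 to 0.926) and 0.0390 for endothelial markers (0.00019 to 0.926). Over all alternatives, the medians ran from 0.12 to 0.38 for macrophage markers, from 0.17 to 0.41 for the cell cycle and from -0.29 to -0.12 for endothelial markers. The direction was not the same within every slide. The median of the macrophage list was -0.46 on slide 1 and -0.36 on slide 3, against 0.42, 0.26 and 0.80 on slides 2, 4 and 5. Slide 1 compares 1 No NR mouse, with a macrophage list mean of -0.63, with 2 Ctrl NR mice at -1.24 and 0.70. The cell cycle list had medians of -0.10, 0.33, -0.15, 0.15 and 0.58 on slides 1 to 5, and the endothelial list 0.33, -0.21, 0.03, -0.17 and -0.45. The endothelial call was lost without any of 7 single mice, with an adjusted p of 0.101 without Ctrl NR 104, 0.127 without Ctrl NR 75, 0.110 without Ctrl NR 95, 0.0957 without No NR 114, 0.0982 without No NR 81, 0.134 without No NR 90 and 0.0851 without No NR 94.

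**Figure D3:**
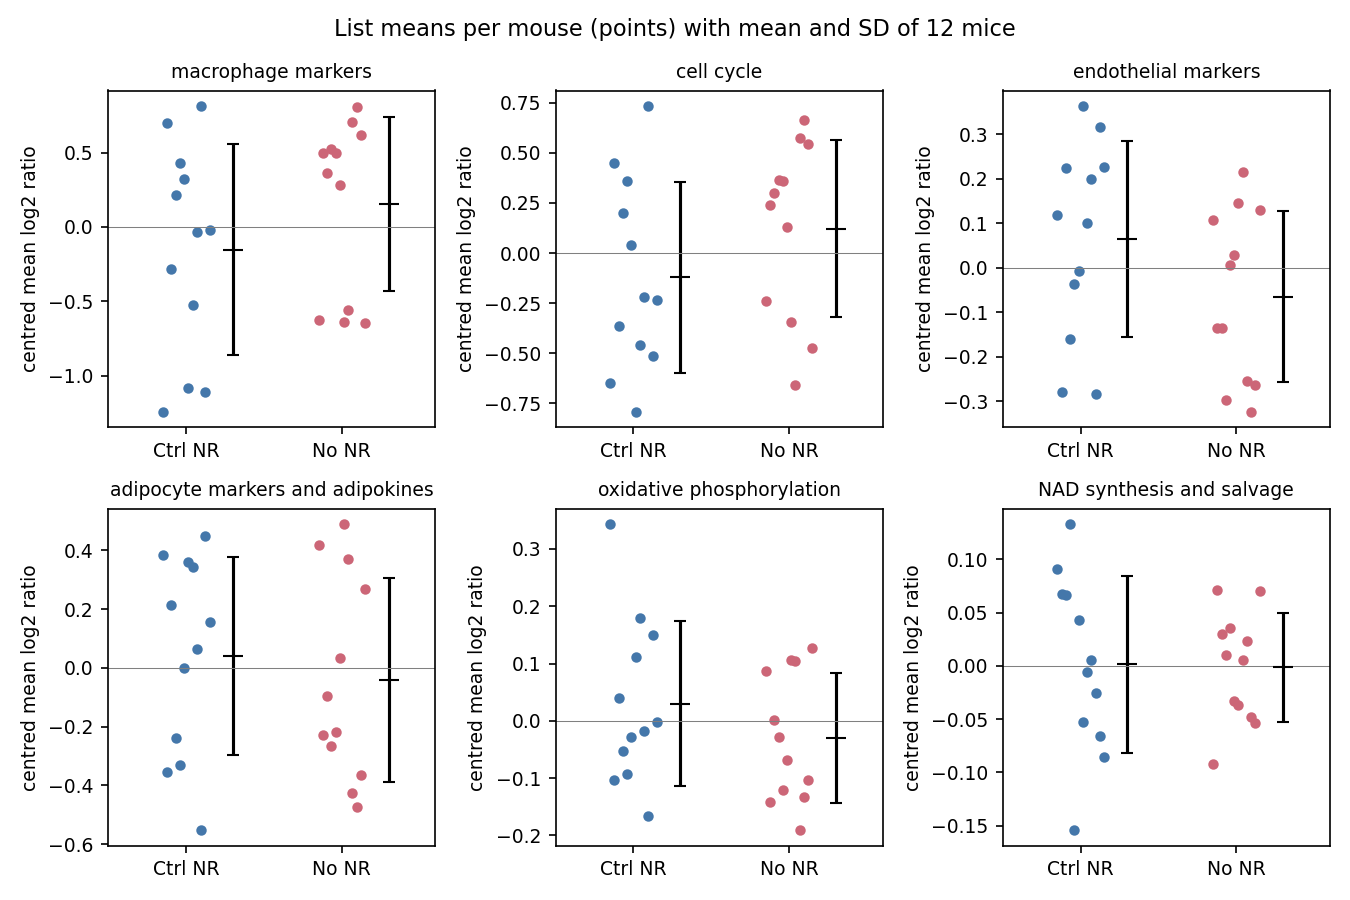
Mean log2 ratio of the measured members of 6 gene lists in each mouse, every gene centred over the 24 mice (vertical axis), by diet (horizontal axis); black bars are mean ± SD of 12 mice. The macrophage list runs from -1.24 to 0.82 in Ctrl NR and from -0.65 to 0.81 in No NR mice.

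The oxidative phosphorylation, adipocyte and de novo lipogenesis lists had medians below 0 but did not pass, and the TCA cycle list, with 10 genes higher and 10 lower, had a median of 0.00 (camera adjusted p = 0.544). Of the 53 measured nuclear-encoded genes of oxidative phosphorylation, 37 were lower, with a median of -0.06 (camera adjusted p = 0.0587, adjusted p = 0.926 with an estimated correlation). Uqcrc1, a core subunit of complex III, was at -0.38 (SE 0.0949, 0.766-fold), from 0.39 ± 0.31 to 0.01 ± 0.14, and was the 1 member that passed adjusted over the list alone (p = 0.0210, limma adjusted p over all genes 0.0826). Within diets, Uqcrc1 followed the mean of the 56 features around probe A_55_P2138100 (r = 0.563) more closely than the macrophage list mean (r = -0.181). Cox8b, a complex IV subunit, was at -0.36 (limma adjusted p = 0.197). Of the 28 measured adipocyte markers and adipokines, 20 were lower, with a median of -0.11 (camera adjusted p = 0.316). The transcription factor gene Cebpb was at -0.35 (limma adjusted p = 0.188), Pparg at -0.16 (-0.37 to 0.04) and Lep, which encodes leptin, at 0.26 (-0.06 to 0.57). Adipoq, which encodes adiponectin, was at 0.01 (-0.42 to 0.44) in 10 Ctrl NR and 12 No NR mice, with that sign in 27 of 41 alternative settings. Its spot was an outlier in Ctrl NR 115 and 104, whose adipocyte list means were 0.38 and 0.21, above the Ctrl NR average of 0.04, so the estimate leaves out 2 mice with high adipocyte transcripts. Ppargc1a, a coactivator of mitochondrial genes, was at -0.01 (-0.15 to 0.14), with that sign in 32 of 41. Among 21 genes of de novo lipogenesis, 14 were lower, with a median of -0.06 (camera adjusted p = 0.812). The acyl-CoA synthetase gene Acsl5 was at 0.41 and the lipogenic regulator Srebf1 at -0.42 (limma adjusted p = 0.140 and 0.204). Within diets, Acsl5 opposed the mean of the 56 features (r = -0.783) and followed the macrophage list mean (r = 0.634). Also within diets, Srebf1 (r = -0.827) and Cox8b (r = -0.612) opposed the macrophage list mean, and Lep opposed the mean of the 56 features (r = -0.641).

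Lists of fat-cell metabolism moved with the macrophage list from mouse to mouse in both diets. Across the 24 mice, the macrophage list mean correlated with the means of the oxidative phosphorylation (r = -0.931, rho = -0.924) and adipocyte lists (r = -0.938, rho = -0.950), and with those of the endothelial (r = -0.851, rho = -0.866) and cell cycle lists (r = 0.951, rho = 0.961). The permutation p of each was 1e-05, the smallest they can give, with adjusted p-values over 38 lists of 2.37e-05 for r and 2.24e-05 for rho. Without the 2 mice farthest from the median, r was -0.924, -0.947, -0.872 and 0.960 in the same order. Within Ctrl NR it was -0.923, -0.925, -0.805 and 0.941, within No NR -0.933, -0.974, -0.894 and 0.961, and with slide removed -0.932, -0.945, -0.891 and 0.957.

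Of the 21 measured circadian clock genes, 7 were higher and 14 lower, with a median of -0.04 (camera adjusted p = 0.486). Nr1d2, which encodes the nuclear receptor REV-ERB beta, passed adjusted over the list alone (p = 0.0408). It was at 0.30 (SE 0.0935), with the same sign on all 5 slides, and over all genes its limma adjusted p was 0.159. Over all 39 lists, 7 members passed adjusted over the list alone and 0 passed over all genes. Besides Uqcrc1 and Nr1d2, these included 4 genes named after their values were seen: the propionyl-CoA carboxylase gene Pccb at -0.34, the p53 target Bbc3 at -0.31, the decorin gene Dcn at 0.42 (11 mice per diet) and the ester lipase gene Cel at 0.27.

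The 36 lists that did not pass had medians from -0.21 for epididymis and testis markers (6 of 34 genes measured, camera adjusted p = 0.428) to 0.17 for inflammatory cytokines and chemokines, where 19 of 23 genes were higher (camera adjusted p = 0.0587, adjusted p = 0.926 with an estimated correlation). Of 22 genes of branched-chain amino acid breakdown, 18 were lower, with a median of -0.08 (camera adjusted p = 0.0647). In 6 lists the signs of median, mean and camera direction were not all the same. The medians of fatty acid oxidation (-0.05) and glycolysis (-0.02) were below 0 where camera gave a higher rank than other genes. Interferon-stimulated genes and endoplasmic reticulum stress genes had medians of -0.00138 and -0.0112, but means of 0.0110 and 0.0185 and an upward camera direction. Immediate early and skeletal muscle genes had medians of -0.05 and -0.04 and a downward camera direction, but means of 0.000839 and 0.00414.

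**Figure D4:**
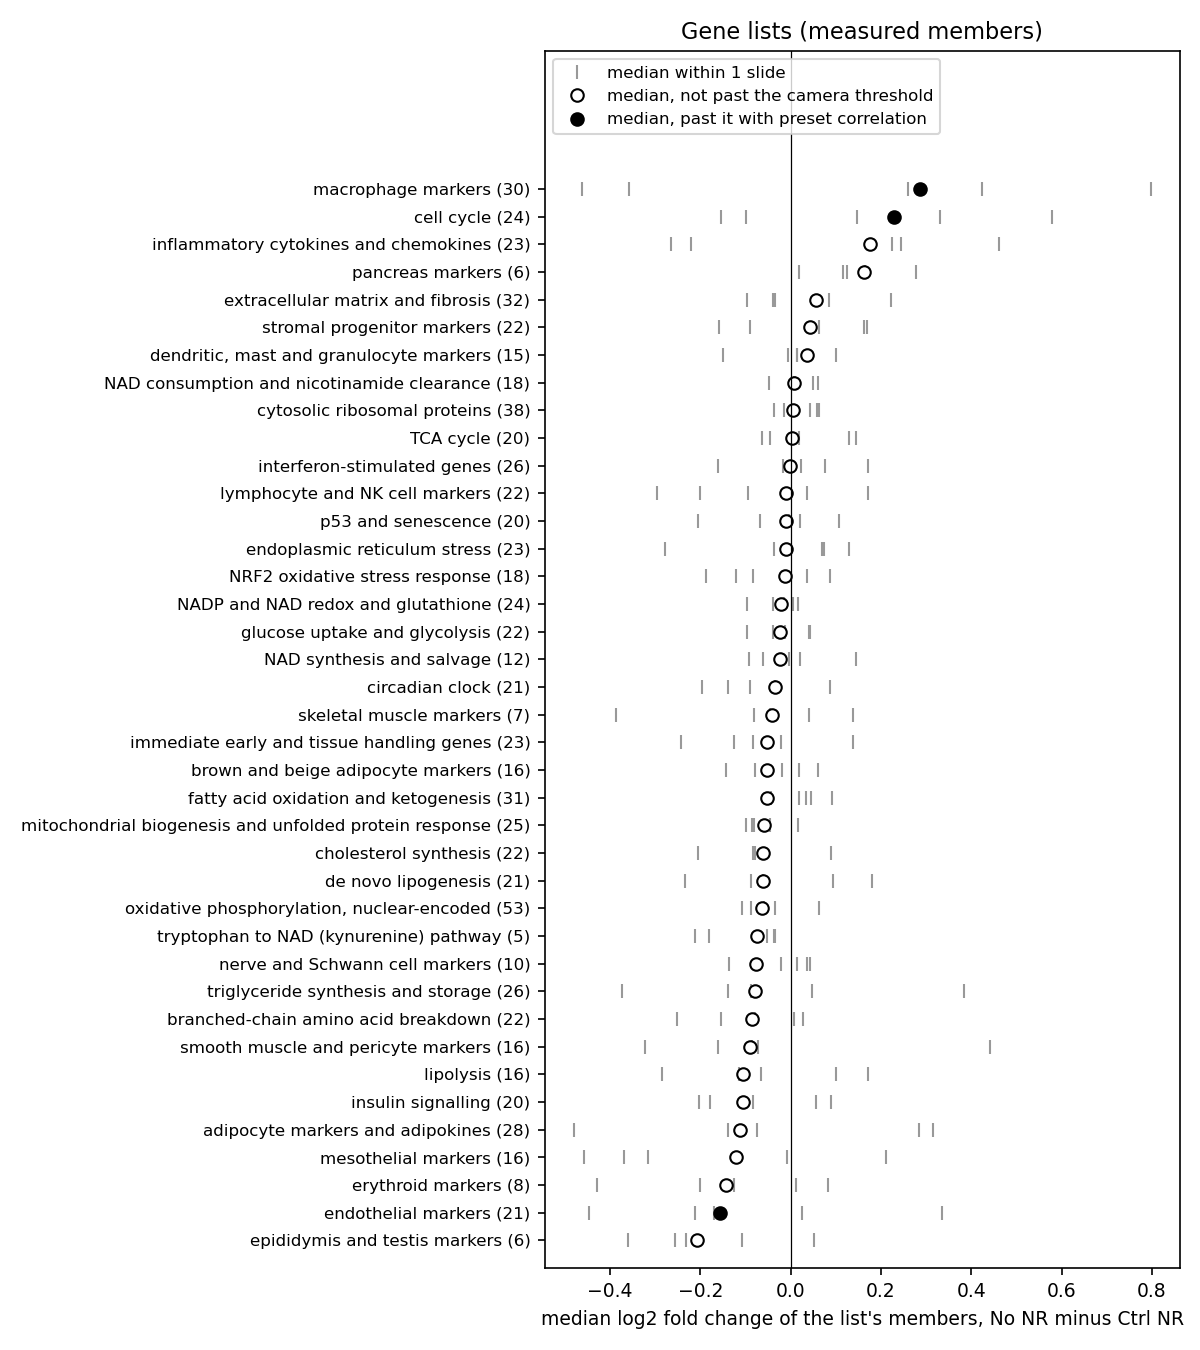
Median log2 fold change (No NR minus Ctrl NR, horizontal axis) of the measured members of each of the 39 gene lists (number in brackets), with the medians within each of the 5 slides as grey ticks. Filled circles mark macrophage markers (0.29), cell cycle (0.23) and endothelial markers (-0.16), which passed camera with the preset correlation; the slides differ in sign for all 3.

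The count of 0 genes depended on single mice and on the weight given to arrays. Without Ctrl NR mouse 68, limma called 228 genes at an adjusted p under 0.05, without Ctrl NR 117 it called 220, without Ctrl NR 104 it called 80, without Ctrl NR 75 it called 34, without Ctrl NR 77 it called 9, and without No NR 78 or No NR 118 it called 3 and 2, whereas the other 17 omissions gave 0. Ctrl NR 68, 117, 104 and 77 had log2 ratios of -1.18, -1.28, -1.26 and -1.42 for probe A_55_P2138100, within the range of the No NR mice (-1.83 to -0.73). Ctrl NR 75 was at 1.09. Whether the calls without single mice reflect diet or the features around that probe was not tested. With estimated array weights it called 205, 78 higher and 127 lower, with Anp32a, Mta1 and Rtl8a among the lower.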

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

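Tests of slide, the reference channel, a single locus, epididymal RNA, single probes, the macrophage axis, the share of adipocyte RNA, the splits for 0 genes, the splits within slides, what the splits follow and the shared axis in other splits were chosen only after the result was seen; the other splits and the test of a shared axis between the diets were chosen before, although the probe that sets this axis was picked after its values were seen.

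In the Cy3 channel, which the comparison of diets uses only as a denominator, 13 probes were well above background on all 24 arrays while their Cy5 signal was so on none; no probe had the opposite pattern (0). 6 of them are Xist probes, the RNA of the silenced X chromosome of females, whose RefSeq-named probe A_52_P113537 had a median Cy3 signal of 109.5 beside a median Cy5 signal of 37.8. The others are the homeobox genes Hoxa10, Hoxa11 and Hoxc10, the antisense gene Hoxa11os, the phosphatase gene Ptpn5 and 2 unnamed probes.

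The number of features at an unadjusted p under 0.05 exceeds the 1053 expected on average with no effect, but with median centring it was 264. Chance cannot be excluded: 5 of 100 splits of the 24 mice into 12 and 12, the real one included, gave at least the real 2968. The other splits had a median of 796, and the highest gave 5938. Slide held from 3.89% to 26.7% of the variance of the 4 other splits, against 6.67% for the diets, and among splits that keep the number of mice per arm on each slide, with slide as a block, 7 of 100, the real one included, gave at least the real 2779 (highest other 4909), so chance cannot be excluded within slides either. For the 0 genes at an adjusted p under 0.05 such a count decides nothing, since all 100 splits must give at least 0, but the 3029 of the highest other split point to a structure among the mice, and that split correlated with the macrophage list mean (absolute r = 0.706) and with the mean of the 56 features described below (0.459). With array weights, 3 of 50 splits, the real one included, gave at least the 205 genes of the diets, with 4154 in the highest other split, so chance cannot be excluded there either. Outside the 56 features that follow or oppose probe A_55_P2138100, 87.8% of the 2917 features at an unadjusted p under 0.05 differed between diets in the way that their slope on these 56 features within a diet predicts, but the same steps gave at least as much in 12 of 100 splits, the real one included (median of the others 62.6%, highest 95.9%), so an axis among mice of the same diet and a difference between diets cannot be told apart.

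Macrophage and cell cycle genes were higher and endothelial genes lower without NR under camera's preset correlation, but none of the 3 lists passed with an estimated correlation (adjusted p = 0.926 for each). 80 of 100 splits of the mice, the real one included, gave at least 3 lists past the threshold, with 26 in the highest other split, so chance cannot be excluded. The macrophage list mean did not differ between diets beyond the spread among mice (permutation p = 0.263), which is consistent with mouse-to-mouse variation present in both diets. A lower share of adipocyte RNA alone would raise macrophage and endothelial markers together, whereas over the 24 mice their list means correlated at r = -0.851. Erythroid markers also opposed the macrophage list mean (r = -0.755). Stromal progenitor (r = 0.737), nerve and Schwann cell (r = 0.684) and dendritic, mast and granulocyte markers (r = 0.842) rose with it. These relations between mice hold within each diet as well, so they do not decide whether the share of adipocyte RNA differs between the diets. An effect of diet on macrophage transcripts stays open, and the spread among mice does not limit it to a small one. Macrophage number was not measured.

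The 56 features around probe A_55_P2138100, 32 that follow it within diets, itself included, and 24 that oppose it (r over 0.8 in size), separate some Ctrl NR mice from all No NR mice; their mean differed by -0.61 (SE 0.166). The tables argue against slide, since the difference was -0.61 (SE 0.180) with slide as a block, and against the reference, since in Cy5 alone it was -0.59 (95% interval -0.96 to -0.23) and in Cy3 alone -0.02 (-0.16 to 0.12). The 24 named genes lie on 15 chromosomes, but the other features, the leading probe among them, have no gene name and were not placed. Features that follow a single locus could also lie elsewhere, so this count does not decide whether 1 locus leads the set. The epididymis and testis list, with 6 of 34 genes measured, correlated with the set at r = -0.169 within diets (95% interval -0.543 to 0.261), which argues against RNA of those organs. However, 1 probe each of Defb36 and Fmr1nb, 2 genes with names typical of those organs and singled out after their values were seen, is in the set (r = 0.819 and 0.876 with the probe). Their other probes, well above background on 1 and 0 arrays, correlated with the set at r = 0.281 and 0.0301. Whether the signal is specific to single probes cannot be told apart, as only 3 other probes of the same genes were measured (median r = 0.568). An RNA or labelling batch that the labels do not record, and diet itself acting in part of the mice, stay open and were not tested.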

How the results depend on the processing

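Array weights by REML, leaving out the arrays of low weight and the macrophage covariate were added after the data were seen. Of the 14 planned settings besides single mice, 11 gave 0 genes at an adjusted p under 0.05, among them Aquantile, which leaves log ratios as they are and so tests nothing. The exceptions were the filter requiring all 24 arrays (3 genes) and the intensity trend with robust variances (3), both Anp32a, Mta1 and Rtl8a, and array weights (205). Array weights by REML gave 275, the macrophage covariate 72, and leaving out the 3 arrays of weight under 0.6 gave 2 (Mta1 and Rtl8a); all 3 are Ctrl NR arrays. Leaving out single mice gave from 0 to 228 genes: 228 without Ctrl NR 68, 220 without Ctrl NR 117, 80 without Ctrl NR 104, 34 without Ctrl NR 75, 9 without Ctrl NR 77, 3 without No NR 78 (Anp32a, Mta1 and Rtl8a), 2 without No NR 118 (Anp32a and Mta1) and 0 without each of the other 17. The count at an unadjusted p under 0.05 ran from 2494 to 3705 over these omissions, and was 264 with median centring and 4557 with no filter, which tests 49106 features. Of the tests at that p, 48.7% were higher in the main setting, 59.8% with no background subtraction, 59.0% in Cy5 alone and 31.8% with median centring.

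Lists past the threshold numbered 0 with camera's estimated correlation and with fry, 1 with the filter on all 24 arrays, 5 in Cy5 alone and with means over probes, 6 with no filter and with single probes, 7 without the arrays of low weight, 11 with array weights and 16 with median centring. Without single mice they ran from 2 to 8: 8 without Ctrl NR 64, 7 without Ctrl NR 88, 6 without Ctrl NR 117 or 84 or No NR 118, 74, 78 or 98, and 5 without Ctrl NR 108 or 97. With median centring the glucose uptake and glycolysis list (-0.19) and the cytosolic ribosomal proteins (-0.22) turned to a called decrease. Oxidative phosphorylation passed in 19 of 41 settings, inflammatory cytokines in 16 and branched-chain amino acid breakdown in 12. Fewer tested features, more tested features and fewer mice are part of the filters and omissions; for the other settings the cause was not tested. Each of the 12 genes with the lowest p kept its sign in all settings that measured it, and Mta1 passed in 13 of 41, Anp32a in 12 and Rtl8a in 12. Sizes varied more: the processed signals gave 0.71 for Dpy19l4, 0.87 for Cenpa and 0.58 for Tpx2, the macrophage covariate gave 0.21 for Cenpa and 0.15 for Tpx2, and the mean over probes gave -0.43 for Anp32a. Genes whose sign varied were Nmrk1, Adipoq, Cd38, Ppargc1a, Nnmt and Nampt, of which none passed in any setting. With a median of 44.7% of spots above background in Cy5, dim genes were not measured.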

Other observations

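The relations below were chosen after the data were seen. Across the 24 mice, the first principal component held 32.5% of the variance and followed the macrophage list mean (r = 0.99), which spanned 4.17-fold between mice. Neighbouring mice lay at most 0.43 apart over both diets; within Ctrl NR 3 mice lay at or below -1.08 and 9 at or above -0.53, and within No NR 4 at or below -0.56 and 8 at or above 0.28, and whether the mice form clusters was not tested. Of 38 other lists, each without genes shared with the macrophage list, 27 were related to it at an adjusted permutation p under 0.05, 12 positively and 15 negatively. Besides the lists already described, lipolysis genes were lower in mice with high macrophage transcripts (r = -0.958, rho = -0.951, permutation p = 1e-05 for both, the smallest they can give, adjusted p = 2.37e-05 and 2.24e-05). This relation held without the 2 mice farthest from the median (r = -0.954), within Ctrl NR (r = -0.947) and No NR mice (r = -0.973), with slide removed (r = -0.960) and on the largest slide (r = -0.971, 6 mice); the other slides hold too few mice.

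Branched-chain amino acid breakdown (r = -0.914, rho = -0.915), de novo lipogenesis (r = -0.896, rho = -0.883) and the circadian clock (r = -0.857, rho = -0.894) were also lower in mice with high macrophage transcripts. Inflammatory cytokines (r = 0.952, rho = 0.915), extracellular matrix genes (r = 0.868, rho = 0.802) and p53 and senescence genes (r = 0.863, rho = 0.792) were higher. Each had a permutation p of 1e-05 for r (adjusted p = 2.37e-05) and, except the extracellular matrix list (2e-05, adjusted p = 4.22e-05), for rho (adjusted p = 2.24e-05). Without the 2 mice farthest from the median, r was -0.900, -0.859, -0.823, 0.945, 0.841 and 0.881 in the same order. Within Ctrl NR it was -0.898, -0.910, -0.833, 0.951, 0.829 and 0.902, within No NR -0.925, -0.908, -0.876, 0.954, 0.918 and 0.929, and with slide removed -0.909, -0.907, -0.854, 0.967, 0.879 and 0.849. The immediate early and tissue handling list followed the macrophage mean as well (r = 0.813, rho = 0.820, permutation p = 1e-05 for both, adjusted p = 2.37e-05 and 2.24e-05), with r = 0.838 without the 2 mice, 0.811 within Ctrl NR, 0.874 within No NR and 0.836 with slide removed. In contrast, the NAD synthesis list was not related to it at the threshold (r = 0.0412, rho = 0.0487, permutation p = 0.847 and 0.820, adjusted p = 0.858 and 0.890; r = 0.108 without the 2 mice, 0.0115 within Ctrl NR and 0.120 within No NR).

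Among 15 single genes fixed for naming, 4 were related to the macrophage list mean at an adjusted permutation p under 0.05. Pparg (r = -0.862, rho = -0.853) and, in the 22 mice that measured it, Adipoq (r = -0.889, rho = -0.903) were lower in mice with more macrophage transcripts (permutation p = 1e-05, adjusted p = 7.5e-05 for each). Parp1 (r = 0.673, rho = 0.716, permutation p = 0.00033 and 0.00017, adjusted p = 0.00165 and 0.00085) and Nmnat3 (r = 0.590, rho = 0.662, permutation p = 0.00239 and 0.00051, adjusted p = 0.00896 and 0.00191) were higher. Without the 2 measured mice farthest from the median, r was -0.811 for Pparg, -0.945 for Adipoq, 0.641 for Parp1 and 0.593 for Nmnat3, and with slide removed -0.905, -0.928, 0.728 and 0.580. Within Ctrl NR the 4 values were -0.825, -0.881 (10 mice), 0.609 and 0.473, and within No NR -0.900, -0.956, 0.768 and 0.709. Lep was not related to it at the threshold (r = -0.177, rho = -0.154, permutation p = 0.408 and 0.469, adjusted p = 0.588 and 0.541).

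Unnamed probes and named genes leaned opposite ways in the comparison of diets, a contrast that was not tested. At an unadjusted limma p under 0.05, 888 unnamed probes were higher and 388 lower in No NR mice, against 558 named genes higher and 1134 lower.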
